A study of Mus musculus with 12 samples.

How the data were processed

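RNA sequencing had been done on 12 libraries of BV-2, an immortalised mouse microglial cell line, in 4 groups of 3: untreated control, lipopolysaccharide (LPS, a bacterial cell wall component that activates microglia), nicotinamide mononucleotide (NMN, a precursor of NAD) and LPS with NMN. Groups and replicate numbers were taken from the sample titles. Doses and times were not given in the sources used here. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

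The file of each library, as deposited by the authors, is a catalogue of transcript events and holds no read count, no expression level and no depth. Per the file headers, each line names an event, its type, gene, chromosome, start, end and strand. The types are first exons (TSS), last exons (TTS), skipped exons, retained introns and alternative exon ends, the last 3 with exact and approximate forms. The submitters' processing notes name GRCm38, BWA 0.7.12, MACS2 2.1.0 and HOMER. The program that made the catalogues is not given in the sources used here. The values analysed are numbers of listed events, which are not expression levels. A gene can be missing from a catalogue because it was not expressed, because too few reads covered it, or because no spliced transcript was assembled. Of the GENCODE M21 protein-coding genes with 1 exon, 6.33% were listed, against 67.1% of those with more exons.

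The positions in the files are not on the build the notes name. Of 16599 distinct exactly skipped exons, 242 (1.46%) lay at the position of a GENCODE M21 exon on GRCm38. In the 2394 genes with 3 or more such exons, 7012 of 10066 exons (69.7%) had the length and spacing of annotated exons after 1 shift per gene, and the best shift was 0 in 50 genes. Event positions are therefore printed as the files give them, on a mouse assembly that is not named, and were not converted. Gene positions are from GENCODE M21 on GRCm38. Of the 14275 gene names in the catalogues, 13939 are in that annotation.

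Skipped-exon and retained-intron events are listed as a pair of lines with and without the event; each pair was counted once, and 9998 repeated lines were left out. The pattern field of all 113240 partner lines of skipped exons carries commas between digit groups, as a spreadsheet would write them, and was not used. First and last exons were matched between libraries by type, gene and pattern, other events by type, gene, start and end. An event listed in both its exact and its approximate form was counted once in each. Alternative ends of the same exon were counted as separate events. The number of distinct events per gene and library was the value tested. A listed gene had at least 2 events, and 32.6% of listed genes had 2, so that a gene moves from 0 to at least 2 when it enters a catalogue.

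The design fixed before the data were examined expected read counts or normalised expression. As the files hold neither, the test written there for values that are not counts was used: limma 3.58.1 in R 4.3.3, with trend and robust empirical Bayes moderation, on log2(events + 1), in 1 model with a mean for each of the 4 groups and 8 residual degrees of freedom. Genes needed at least 1 event in 3 libraries; 1500 genes fell below this, 1104 had the same number of events in all 12 libraries and could not be tested, and 11671 were tested. P-values were adjusted by the Benjamini-Hochberg method at 0.05. Differences are on the log2(events + 1) scale and no fold is given against a group in which a gene was not listed. The scores in CPM that the design foresaw could not be computed.

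The rule for named genes, also fixed before the data were examined, takes up to 10 genes raised and 10 lowered per comparison, by size of difference among those past the threshold, with groups that do not overlap, a mean of at least 1 event, and no predicted or clone name; for the interaction, the 5 highest and 5 lowest; a set of anchor genes of ferroptosis, NAD metabolism and inflammation whatever their value; and up to 4 members of each list described. Genes outside it are said to have been chosen after their values were seen. Of 39 gene lists fixed in advance, 38 had at least 3 tested members and were tested with limma's camera with a preset correlation of 0.01. Members under older symbols were matched through RefSeq synonyms.

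On simulated data without group differences, drawn from each gene's own 12 values, with 200 of about 11039 genes changed in each of 5 runs of LPS against control, 99.4% of genes removed from a group, 45.4% of 2-fold and 90.9% of 4-fold changes in event number were called. The changed genes were drawn only from those with a mean of at least 2 events over the 12 libraries. These shares therefore do not cover genes listed in few libraries. Of all simulated calls, 9.25% were false, above the 5% aimed at, so the adjusted p-values of limma here are somewhat too small. Without trend and robust moderation the false share was 10.8%. In 5 runs of a contrast without change, 13 genes were called in all.

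Listing was also counted directly, as genes or events present in all 3 libraries of one group and none of the other, and compared with the other ways to split the same libraries (exact permutation, 10 splits of 3 against 3, smallest p 0.1). Return toward control was set against simulated draws in which the LPS and LPS+NMN groups shared 1 mean and the residuals were shuffled over libraries. This simulation, the count of listings, the comparisons of LPS+NMN with NMN and of NMN with LPS, and the controls against all 9 treated libraries were added after seeing the data. Alternatives were quantile normalisation, limma without trend and robust moderation, both filters, a pseudocount of 0.1, only the groups compared, the replicate number as a block and leaving out each library; catalogue size (the number of events) or the number of genes listed as a covariate and splicing events alone were chosen after seeing the data. Alternatives that need counts were not run. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.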

Results

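The transcript catalogues of 12 BV-2 libraries listed 14275 genes in all, of which 10858 were in every library. A library held between 11911 and 12246 genes and between 50784 and 55787 distinct events, of which between 16389 and 19724 were splicing events (skipped exons, retained introns and alternative exon ends) and the rest first and last exons. Genes listed averaged 12066 ± 169 in control, 12139 ± 62.3 in LPS, 12151 ± 96.1 in NMN and 12150 ± 39.8 in LPS+NMN libraries (SD, n = 3). The largest catalogue was that of control replicate 1. Sequencing depth is unknown, so no counting error can be attached to a listing. Events present in 1 library alone made up 44.0% of the 141591 distinct events.

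LPS was compared with control to measure the response against which NMN is set. The catalogues of LPS-treated cells gained interferon-response genes and single cytokine genes such as Il12b and Il36a. Ifit3b, an interferon-induced gene, Zbp1, a sensor of nucleic acids, and Il12b, a subunit of interleukins that drive T cell responses, were in all 3 LPS libraries and in no control library. Irf7, a transcription factor that amplifies type I interferon production (chromosome 7, 141262706 to 141266481, minus strand, GRCm38), rose from 7.67 ± 1.15 events in control to 15.7 ± 0.577 with LPS (SD, n = 3), a log2 difference of 0.95 ± 0.14 (SE, limma adjusted p = 0.00869). Slfn4, a myeloid gene of a family induced by interferon, rose from 4 ± 2 to 16.3 ± 0.577 events, and Mx2, an antiviral GTPase, from 2.33 ± 0.577 to 6.67 ± 1.15. Among 11671 genes, limma called 30 with more and 5 with fewer events after LPS at an adjusted p of 0.05. Of the 30, 24 were not listed in any control library.

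The genes with the largest gains by the naming rule were Ntng2, a membrane protein that guides axons, with 20.3 ± 3.79 events in LPS and none in control, and Apol9b, with 4.67 ± 1.15. Il36a, a cytokine of the interleukin-1 family, had 4.33 ± 0.577 events, H2-M2, a class I histocompatibility gene, 3.33 ± 0.577, and Urah, a hydrolase of the uric acid pathway, 3 in each LPS library; none was listed in control. Mmp3, a matrix metalloprotease, Serpina3f, a serine protease inhibitor, Slc26a4, an anion exchanger, and Stfa3, a cysteine protease inhibitor, each had 2.33 ± 0.577 events against none. Apol9b, Ifit3b, H2-M2, Serpina3f, Stfa3 and Slfn4 belong to families of similar genes, and reads may have been shared with relatives. The 5 genes with fewer events were Cfap77, Capn9 and Serpinb10, each in all control and no LPS library, Chst3, a sulfotransferase (5 to 2 events), and Galk2 (10.3 ± 0.577 to 4.67 ± 1.15). Slfn4 was called in 7 and Galk2 in 5 of 16 alternative settings, and Serpinb10 in 4 of 14.

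Of 41 tested members of the type I interferon list, 34 had a higher and 6 a lower mean after LPS; 5 were called over all genes (Ifit3b, Irf7, Mx2, Oasl2 and Zbp1) and 11 adjusted over the list alone. Camera placed the list above other genes (adjusted p = 2.28e-14, and adjusted p = 0.00152 with an estimated correlation). The estimated correlation was 0.01, equal to the preset one, so the gap between these camera p-values does not come from correlation among the members. Listed events of the list rose from 147.3 ± 10.7 per control library to 214.3 ± 10.1 with LPS. The NFkB cytokine and chemokine list, with 35 tested members, had 1 called (Il12b) and 2 adjusted over the list alone (Il12b and Csf3, a granulocyte growth factor); camera gave an adjusted p of 0.0269, and adjusted p = 0.267 with an estimated correlation. The T and B cell marker list went down by camera on 3 tested members (adjusted p = 0.0269, and adjusted p = 0.267 with an estimated correlation), with none called over all genes and 2 adjusted over the list alone (Cd4 and Cd79b). Classical LPS targets were already in the control catalogues: Tnf had 2 events in each control and 2.33 ± 0.577 in LPS libraries, Il1b 2 in both groups, Il6 2.67 ± 0.577 and 3.33 ± 0.577, and Nos2 2 and 4 ± 2, and none of these passed (limma adjusted p = 0.749 for Il6 and 0.518 for Nos2). Without control replicate 1 limma called 49 genes with more events, and without LPS replicate 1 or 3 it called 12 or 11 with fewer. It called 3 with more and 0 with fewer events with a filter of at least 5 events in 3 libraries, and again with splicing events alone, a setting chosen after seeing the data, and 1 and 0 with only the 2 groups in the fit.

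**Figure D1:**
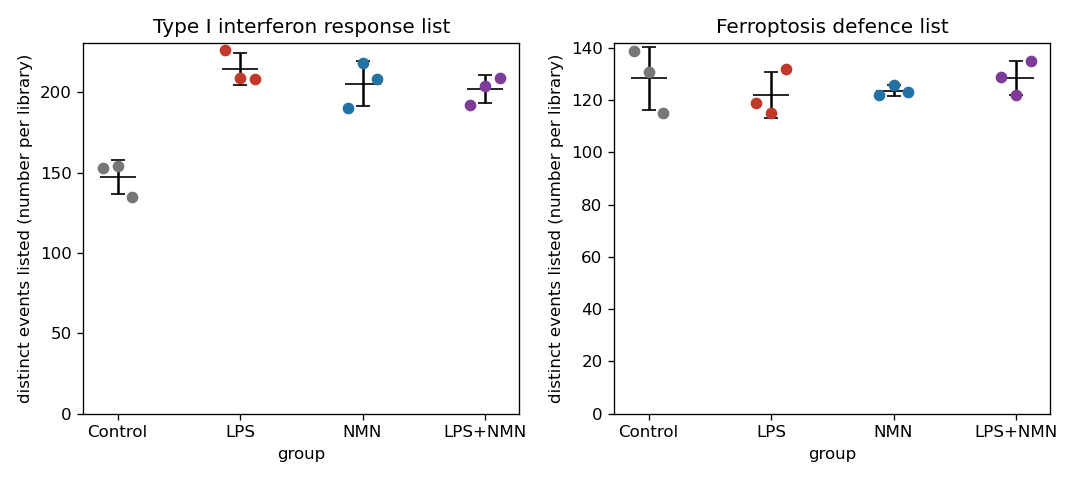
Number of distinct events listed per library (y axis) for members of the type I interferon response list and the ferroptosis defence list, by group (x axis). Points are libraries, the horizontal bar and whiskers the mean and SD of 3 libraries; interferon events average 147.3 in control and 201.7 or more in each treated group, and ferroptosis defence events lie between 122 and 128.7 on average.

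LPS+NMN was compared with LPS, the comparison the series was designed for, to ask which genes NMN changes in LPS-treated microglia. No gene passed limma's threshold in either direction, with 521 of 11671 genes at an unadjusted p under 0.05; limma without trend and robust moderation called 4 with more and 2 with fewer events, and leaving out LPS replicate 1 gave 10 and 1. Gpx4, the peroxidase that detoxifies lipid hydroperoxides and guards against ferroptosis (chromosome 10, 80047166 to 80056439, plus strand, GRCm38), was in all 12 catalogues, with 2.67 ± 0.577 events in LPS and 2.33 ± 0.577 in LPS+NMN (log2 difference -0.14 ± 0.17, limma adjusted p = 0.93). Slc7a11, the cystine importer that feeds glutathione synthesis, had 3.33 ± 0.577 and 3.33 ± 1.15 events, Aifm2, a ubiquinone reductase that also blocks ferroptosis, 3.67 ± 1.15 and 3.33 ± 0.577, and Fth1, the ferritin heavy chain, 4.67 ± 1.15 and 5.33 ± 1.15. Acsl4, which loads membranes with oxidisable lipids, had 7.33 ± 3.79 and 7.67 ± 1.53, and Tfrc, the transferrin receptor, 3.33 ± 0.577 and 3. Hmox1 and Nqo1 had 2 events in every library. A listing says that transcripts of the gene were found and does not measure their level, so these values neither show nor exclude a change in expression.

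None of the 38 lists passed in LPS+NMN against LPS. Of 26 tested ferroptosis defence genes, 0 were called over all genes or adjusted over the list alone, 13 had a higher and 13 a lower mean, and camera gave an adjusted p of 0.874. Of 27 ferroptosis-promoting genes 0 were called (adjusted p = 0.991), of 19 iron handling genes 0 (adjusted p = 0.874), of 25 NRF2 and glutathione genes 0 (adjusted p = 0.735) and of 20 selenoprotein genes 0 (adjusted p = 0.735). Among 19 NAD synthesis genes 0 were called over all genes and 1, the mitochondrial NAD kinase Nadk2, adjusted over the list alone. Nampt, the rate-limiting enzyme of NAD salvage, had 6.33 ± 0.577 events in both groups, Nmnat1 3 in every library, Sirt1 4.33 ± 1.15 and 4.67 ± 1.53, Parp1 2.67 ± 1.15 and 2.33 ± 0.577, and Cd38 2 in both groups. The interferon list had 0 calls over all genes and 3 with fewer events adjusted over the list alone (Gbp7, Ifih1 and Trim30a), with a camera adjusted p of 0.616. The smallest adjusted p was 0.0609, for Capn9 and Cfap77, which returned to the catalogues of LPS+NMN, and Prm2, which left them; these were chosen after their values were seen. Genes listed in all of one group and none of the other numbered 24, fewer than the 27 to 39 of the other 9 splits of these 6 libraries (exact permutation p = 1). By events the labelled split lay near the top of the range instead, with 256 first exons (205 to 257 in the others, exact permutation p = 0.2), 191 last exons (141 to 192, exact permutation p = 0.2) and 364 splicing events (295 to 365, exact permutation p = 0.3).

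NMN was compared with control to describe NMN without LPS. The NMN catalogues also gained interferon-response genes and the single cytokine genes Il12b and Il36a. Ifit3b had 2.33 ± 0.577 events and Zbp1, Il12b and Dnase1l3, a secreted DNase, 2 in each NMN library, and none was in a control library. Irf7 had 15.7 ± 0.577 events against 7.67 ± 1.15 in control (log2 difference 0.95 ± 0.14, limma adjusted p = 0.00869), Ntng2 18.0 ± 3, Apol9b 4.67 ± 1.15, Il36a 3.67 ± 0.577, H2-M2 3.33 ± 0.577 and Urah 2.67 ± 0.577, the last 5 against none. Speer4d, Ifit1bl1 and Stfa3 each had 2.33 ± 0.577 events against none. Limma called 26 genes with more and 1 with fewer events, the latter Fbxo44, a ubiquitin ligase subunit, in all control and no NMN library. All 26 genes were also among the 30 raised by LPS, and 24 of the 26 were listed in no control library. Simulated unchanged groups against the same controls shared 0 on average. As no group differed in those draws, that 0 does not show how many of the 26 come from the shared controls. Independent lists would share 0.0668. Part of the excess may come from the shared controls, which were too few to split. Part may come from the model, which took each gene's spread from all 4 groups. A gene absent from control and steady in all treated groups was thereby called more readily. Of 49 genes in all NMN and no control libraries, 24 were called, and each of these was in all 9 treated libraries. The 0.0668 for independent lists allows for neither source. The covariance of the log2 differences over genes was 0.0966, against 0.0618 on average in 100 simulated draws (range -0.0283 to 0.103).

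In NMN against control, 34 of 41 interferon list members had a higher and 6 a lower mean, 4 were called (Ifit3b, Irf7, Oasl2 and Zbp1) and 7 adjusted over the list alone (camera adjusted p = 9.47e-11, and adjusted p = 0.00425 with an estimated correlation). Events of the list came to 205.3 ± 14.2 per NMN library. The NFkB list did not pass, with 21 of 35 members higher and 12 lower, 1 called and 2 adjusted over the list alone (camera adjusted p = 0.112, and adjusted p = 0.581 with an estimated correlation). The T and B cell list went down on 3 tested members (adjusted p = 0.0192, and adjusted p = 0.215 with an estimated correlation), with 0 called and 1 (Cd79b) adjusted over the list alone. The ferroptosis defence list had 0 of 26 called (adjusted p = 0.869), with Gpx4 at 2.33 ± 0.577 events against 2 in each control. NAD synthesis had 0 of 19 called (adjusted p = 0.97) and NAD consumers 0 of 27 (adjusted p = 0.869). NMN set directly against LPS gave no call by limma in either direction, with 577 genes at an unadjusted p under 0.05 and 4 and 2 calls without trend and robust moderation. In NMN against control limma called 42 genes with more events without control replicate 1, and between 2 and 5 with fewer when any 1 library was left out. It called 3 and 0 with at least 5 events in 3 libraries, 2 and 0 with splicing events alone, and 1 and 0 with only the groups compared.

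LPS+NMN was compared with control to see what stayed different under both treatments. Limma called 33 genes with more and 6 with fewer events. Ntng2 had 28.3 ± 8.62 events, Apol9b 5.67 ± 0.577, Il36a 4.33 ± 0.577, Urah 3.33 ± 0.577, H2-M2 3 and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, 2.33 ± 0.577, all against none in control. Gipr, the receptor of a gut incretin, rose from 2 to 14.3 ± 0.577 events and Ifi206, an interferon-induced gene, from 0.667 ± 1.15 to 6 ± 1.73. Prm2 and Serpinb10 left the catalogues, Pcmtd2 went from 9.67 ± 2.08 to 3 events and Chst3 from 5 to 2, and Ak8 and Clasp2 were also called lower. Of 16 alternative settings, Ifi206 was called in 4, Clasp2 in 6, Ak8 in 8 and Pcmtd2 in 8, and Serpinb10 was called in 4 of 14. Of the interferon list, 3 members were called (Ifit3b, Irf7 and Zbp1) and 12 adjusted over the list alone (camera adjusted p = 1.29e-08, and adjusted p = 0.00903 with an estimated correlation). Its events came to 201.7 ± 8.74 per library. With the replicate number as a block 3 genes were called lower instead of 6, and 3 with the number of genes listed as a covariate. With at least 5 events in 3 libraries 8 genes were called higher and 2 lower, with splicing events alone 8 and 0, and with only the groups compared 3 and 0.

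Return toward control was measured on the 35 genes called in LPS against control. As limma called 0 genes in LPS+NMN against LPS, 0 of the 35 could be called in either direction, so the count of calls does not measure return. At an unadjusted p under 0.05, 7 of the 35 (20%) differed in the opposite direction; of all differences 14 pointed against the LPS effect (40%), 7 with it and 14 were 0. Both comparisons use the LPS libraries, which gives opposite differences without any effect of NMN. In 100 simulated draws in which LPS acted and NMN added nothing, a test chosen after seeing the data, 15.2% of LPS-called genes on average (0 to 41.9%) were opposite at an unadjusted p under 0.05, and 39 draws gave as large a share. Differences against the LPS effect made up 59.5% on average (14.3 to 85.6%), and differences of 0 18.9% (6.06 to 42.9%) against 40% observed, a share that 3 draws reached. Event numbers are whole and the simulated values are not, which limits the comparison of exact zeros. These draws called 28 to 377 genes in LPS against control, 126 on average against the 35 observed, so they match the observed genes only roughly. Over all genes tested, which are not independent replicates, the log2 differences correlated at -0.418, against -0.469 on average in 100 simulated draws of unchanged groups, and their covariance was -0.0565, against -0.0613 (range -0.0959 to 0.0286). Without LPS replicate 1, 22.4% of the LPS-changed genes were called in the opposite direction. The LPS effect measured in the presence of NMN, LPS+NMN against NMN, shares no library with LPS against control. Over the 35 genes its slope on the LPS effect was 0.07 (Pearson r = 0.545 across genes, which are not independent replicates). The 30 raised genes had a median log2 difference of 1.58 in LPS against control and 0 in LPS+NMN against NMN. Their median was also 1.58 in NMN against control and in LPS+NMN against control, and 0 in LPS+NMN against LPS. These genes were thus already higher with NMN alone, and their 0 does not show a return toward control. The 5 lowered genes had medians of -1.585, -0.138 and -0.509 in LPS, NMN and LPS+NMN against control. Genes chosen by 1 estimate also shrink in the other by selection. As no gene was called in LPS+NMN against NMN by limma (531 at an unadjusted p under 0.05, 3 and 3 calls without trend and robust moderation), the reverse choice of genes gave no slope. The interaction, which tests whether the effect of NMN differs with LPS, had 0 genes with a positive and 5 with a negative value: Ntng2 (log2 -3.81 ± 0.33), Apol9b (-2.23 ± 0.26), H2-M2 (-2.21 ± 0.23), Il36a (-2.21 ± 0.20) and Urah (-1.75 ± 0.25). Urah was called in 6 of 19 alternative settings, and the value for Apol9b ranged from -5.25 to 0.528, the latter with splicing events alone. Limma without trend and robust moderation called 10 genes with a positive and 29 with a negative value. All 5 were absent from control and listed in every treated library, and none of them was called in LPS+NMN against LPS or against NMN.

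**Figure D2:**
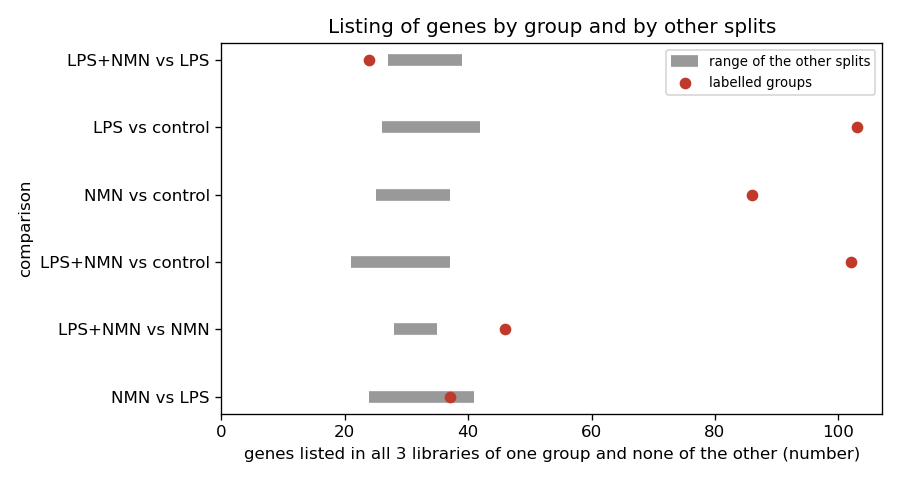
Genes listed in all 3 libraries of one group and none of the other (x axis, number) for 6 comparisons (y axis). Red points are the labelled groups and grey bars the range of the other 9 splits of the same 6 libraries; LPS, NMN and LPS+NMN differ from control by 103, 86 and 102 genes, and LPS+NMN from LPS by 24.

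Counted by listing alone, 65 genes were in all LPS and no control libraries and 38 the reverse, 103 in all against at most 42 in the other splits; NMN against control gave 86 (at most 37) and LPS+NMN against control 102 (at most 37), each with exact permutation p = 0.1, the smallest 3 against 3 allow. LPS+NMN against NMN gave 46 genes (at most 35, exact permutation p = 0.1), but 226 first exons (at most 255, exact permutation p = 0.7), 173 last exons (at most 183, exact permutation p = 0.6) and 325 splicing events (at most 380, exact permutation p = 0.8), and NMN against LPS 37 (at most 41, exact permutation p = 0.4). By events, NMN and LPS were separated by 255 first exons (at most 244), 197 last exons (at most 190) and 372 splicing events (at most 352), each with exact permutation p = 0.1. Over all treated libraries, a pooling chosen after the values were seen, 24 genes were in all 9 and no control and 4 (Gm2296, Irf2bpl, Map1a and Pxylp1) in all controls and no treated library. The highest total of the other splits of 3 against 9 was 10 (exact permutation p = 0.00455, the smallest the 220 splits give). Within genes listed in every library, 68 events were in all 9 treated and no control libraries and 87 the reverse, 155 against at most 74. The 68 events lay in 57 genes, 9 of them from the interferon list (Dhx58, Gbp2, Gbp3, Ifit3, Irf7, Isg20, Parp9, Rtp4 and Trim30a). Fisher's exact test, one-sided, gave an adjusted p = 7.42e-12 over 33 lists, with each gene given the same chance whatever its number of events. Rtp4 also had another first exon in all controls and no treated library. Among the 68 events were an exon of Ifit3 skipped at chromosome 19, 34563674 to 34563780, and one of Dhx58 at chromosome 11, 100594727 to 100594895, in file positions of an unnamed mouse assembly. An exon of Irf7 and one of Parp9 were counted in both the exact and the approximate form. Alternative ends of the same exon were each counted too, as in Adamts6, Carf and Il18 among the 68 and in B4galnt1, Cd151 and Tln2 among the 87. Such pairs were more frequent among the 87, so part of the excess over 68 comes from this counting.

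Markers of other cell types are given as numbers of markers listed per library, in the order control, LPS, NMN and LPS+NMN (SD, n = 3). Of 12 astrocyte markers 3.67 ± 0.577, 4 ± 1, 3.33 ± 0.577 and 3.67 ± 0.577 were listed. Of 14 neuron markers the catalogues held 2.33 ± 0.577, 3 ± 1, 3.33 ± 1.15 and 3.67 ± 0.577, and of 12 oligodendrocyte markers 3.33 ± 0.577, 3.67 ± 0.577, 3.33 ± 0.577 and 3.33 ± 0.577. Endothelial markers, 10 in all, numbered 5 ± 1, 5.33 ± 0.577, 5 and 5, and 11 neutrophil markers 4.67 ± 1.15, 4.33 ± 1.15, 3.33 ± 0.577 and 4.33 ± 0.577. Of 12 T and B cell markers 3, 2 ± 1, 2 and 2.33 ± 0.577 were listed, and of 12 fibroblast markers 1.67 ± 0.577, 4, 2 ± 1 and 3 ± 1.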

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

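The tests of explanations in this part, and the counts of splits, were chosen after the results were seen.

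The effect of NMN differed with LPS in the test of the interaction for 5 genes, each listed in no control and in all treated libraries. The differences (log2, NMN effect with LPS minus without) were -3.81 for Ntng2, -2.23 for Apol9b, -2.21 for H2-M2, -2.21 for Il36a and -1.75 for Urah. Of 100 splits of the samples, 8 gave at least as many genes, and the highest of the others gave 6, so chance is not excluded for this count. The type I interferon list also differed (camera adjusted p = 1.44e-10, and adjusted p = 0.00451 with an estimated correlation), as did the T and B cell marker list on 3 tested members (camera adjusted p = 0.001, and adjusted p = 0.0723 with an estimated correlation). Of the 100 splits, 4 gave as many lists as the 2 found, and the highest of the others also gave 2. A gene absent from control and listed under each treatment gives a negative interaction on this scale unless the combined treatment lists far more events, by the construction of the measure.

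For comparisons of 3 against 3 there are 10 splits, too few for a share under 0.05. LPS against control gave 35 genes and 3 lists, against at most 5 genes and 1 list in the other splits, and 1 of the 10 splits, the labelled one, gave as many in both. NMN against control gave 27 genes and 2 lists (at most 8 and 1 in the others, 1 of 10 as large), and LPS+NMN against control 39 genes and 1 list (at most 5 and 0, 1 of 10). LPS+NMN against LPS gave 0 genes and 0 lists, which all 10 splits reach, while the highest of the others gave 6 genes and 0 lists. LPS+NMN against NMN and NMN against LPS gave 0 genes and 0 lists, as did all 10 splits of each.

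NMN libraries listed genes that the control libraries lacked and that were also called in LPS against the same controls. Of 24 genes in all treated and no control libraries, 2 (Ifit3b and Zbp1) were on the interferon list and 1 (Il12b) on the NFkB list. Whether a difference in catalogue size gave this was not settled by the model. With the number of events in the model limma called 28 genes with more events in NMN against control. With the number of genes listed, of which control had the lowest mean (12066, against 12139 to 12151), it called 26, as without either. Genes such as Zbp1 and Il12b had the same number of events in every library of a group. Size in the model could therefore not change their difference. The largest catalogue, that of control replicate 1 (55787 events, 12246 genes), listed none of the 24 genes, so a small catalogue is not why that library lacked them. The tables argue against labels exchanged between libraries of the series, as 6 libraries are labelled with LPS. Of the interferon list, 9 libraries had 190 to 226 events and 3 had 135 to 154. That gap of 36 compares with a largest SD within a group of 14.2. LPS in the NMN cultures, endotoxin in the NMN, NMN labels on LPS libraries from outside the series, or controls grown or prepared apart from the rest cannot be told apart from an effect of NMN: genes separating NMN from LPS numbered 37, against at most 41 in the other splits, while first exons numbered 255 (at most 244), last exons 197 (at most 190) and splicing events 372 (at most 352), and 10 splits are too few for a share under 0.05. The enrichment of the interferon list among events found in every treated and no control library bears on none of these, since those events were chosen for the pattern. An action of NMN itself on interferon genes stays open and was not tested.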

How the results depend on the processing

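Catalogue size (events) or genes listed as a covariate and splicing events alone, all settings of LPS+NMN against NMN and NMN against LPS, the settings of the listing counts and those of the retained-intron share were chosen after seeing the data. Quantile normalisation and catalogue size as a covariate moved no count of calls by over 1.5 times, and the slope of the LPS effect was 0.0271 with that covariate. With genes listed as a covariate 3 genes instead of 6 were lower in LPS+NMN against control, no other count moved by over 1.5 times, and the slope was 0.0339. No named gene that limma called changed direction except Apol9b in the interaction, at 0.53 with splicing events alone. Read depth, which would limit what a catalogue can list, is unknown. Where a setting changed a count, the cause was not tested unless it is given.

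Limma without trend and robust moderation called 4 genes higher and 2 lower in LPS+NMN against LPS, 9 lower in LPS against control, 5 lower in NMN against control, 11 lower in LPS+NMN against control, 10 higher and 29 lower in the interaction, 3 and 3 in LPS+NMN against NMN, and 4 and 2 in NMN against LPS; 7.5% of LPS-changed genes then moved in the opposite direction. With genes listed in any library, 9, 5 and 10 genes were lower in LPS, NMN and LPS+NMN against control. A pseudocount of 0.1 gave 2 genes higher and 1 lower in LPS+NMN against LPS and in NMN against LPS, and 5.13% in the opposite direction.

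At least 5 events in 3 libraries leaves out genes that a group does not list, unless they have many events: 3 genes were higher and 0 lower in LPS against control, 3 and 0 in NMN against control, 8 and 2 in LPS+NMN against control, 1 was lower in the interaction, and the slope of the LPS effect with NMN on that without was 0.123. Splicing events alone gave 3 and 0, 2 and 0, 8 and 0 in the same order, 0 lower in the interaction, 1 lower in LPS+NMN against LPS and in NMN against LPS, 33.3% in the opposite direction and a slope of 0.118. Only the groups compared, with fewer libraries to estimate the spread, gave 1 and 0, 1 and 0, and 3 and 0. With an estimated correlation 1 list passed in LPS against control, 1 in NMN against control and 1 in the interaction, each the interferon list.

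Leaving out 1 library at a time gave 0 to 10 genes higher and 0 to 1 lower in LPS+NMN against LPS, 27 to 49 and 5 to 12 in LPS against control, 31 to 42 and 2 to 5 in NMN against control, 25 to 47 and 4 to 8 in LPS+NMN against control, 0 to 1 higher and 4 to 6 lower in the interaction, and 0 to 10 and 0 to 1 in NMN against LPS. The 10 genes came without LPS replicate 1, the 49 and 42 without control replicate 1. The opposite share ranged from 0 to 22.4% and the slope from 0.0206 to 0.0767. Genes listed in all of one group and none of the other rose to 61 to 86 for LPS+NMN against LPS, 169 to 187, 138 to 159 and 167 to 183 for LPS, NMN and LPS+NMN against control, 82 to 109 for LPS+NMN against NMN and 74 to 104 for NMN against LPS, since fewer libraries have to agree. The retained-intron difference ranged from 0.485 to 0.59. With retained introns of the exact form alone it was smaller, 0.309 percentage points (exact permutation p = 0.01, adjusted p = 0.03). That difference was 0.288 without LPS (exact permutation p = 0.2) and 0.331 with LPS (exact permutation p = 0.1).

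The replicate numbers share only a number: deviations of same-numbered libraries correlated at -0.0024 on average (-0.0271 to 0.022, 18 pairs), and 4 of 12 libraries correlated best with their own number. With the replicate block limma called 28 genes higher and 5 lower in LPS against control, 25 and 1 in NMN against control, 29 and 3 in LPS+NMN against control (6 lower without it), 0 and 4 in the interaction and 0 in LPS+NMN against LPS. The slope was 0.0527, the retained-intron difference 0.532 (exact permutation p = 0.0312), and 3, 2, 1 and 2 lists passed in LPS, NMN and LPS+NMN against control and in the interaction.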

Other observations

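Camera's test of the homeostatic microglia list was planned; the other tests in this part were chosen after the results were seen.

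Listed events of the homeostatic microglia list averaged 84.3 ± 2.52 per control library, 77.0 in each LPS library, 75.0 ± 7.21 in NMN and 73.7 ± 5.03 in LPS+NMN (SD, n = 3). The difference between 3 controls and 9 treated libraries failed the correction (exact permutation p = 0.00909, adjusted p = 0.118 over 39 lists). Camera did not place the list apart from other genes: 12 members were higher and 11 lower in LPS against control (adjusted p = 0.85), 8 and 14 in NMN against control (adjusted p = 0.839) and 7 and 15 in LPS+NMN against control (adjusted p = 0.503), with 0 called over all genes or adjusted over the list alone in each. The interferon list, tested the same way, had an exact permutation p = 0.00455 and an adjusted p of 0.118, and the NFkB list p = 0.00909 and the same adjusted p, so none passed the correction. With 220 splits 0.00455 is the smallest p, and over 39 lists a single list that reaches it cannot pass. Failing the correction therefore does not speak against a difference in these lists. The 87 events found in all controls and no treated library lay in 63 genes, in which none of 33 lists was enriched (Fisher's exact test, one-sided, smallest adjusted p = 0.606).

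Retained introns took a larger share of splicing events in libraries with NMN. The share was 6.25 ± 0.18% in control, 6.41 ± 0.166% in LPS, 6.75 ± 0.212% in NMN and 6.97 ± 0.0879% in LPS+NMN (SD, n = 3). Within LPS and no LPS, NMN libraries exceeded the others by 0.532 percentage points on average (exact permutation, two-sided, 400 arrangements, p = 0.005, the smallest they can give, adjusted p = 0.02 over 12 measures); within each stratum alone the p was 0.1, the smallest 3 against 3 allow. The skipped-exon share differed by -1.14 percentage points (exact permutation p = 0.005, adjusted p = 0.02), while the number of skipped exons differed by -222.5 per library (exact permutation p = 0.545) and by 73.3 within LPS. Over 12 measures a single measure at the smallest exact permutation p could not pass. The adjusted p of 0.02 rests on overlapping measures that all reached it: the retained-intron share, the skipped-exon share and the share of genes with a retained intron. Retained-intron and skipped-exon shares are parts of the same splicing events and are not separate results. With LPS against without, the retained-intron share differed by 0.194 (exact permutation p = 0.08, adjusted p = 0.32 over 12 measures) and the skipped-exon share by -0.73 percentage points (exact permutation p = 0.035, adjusted p = 0.32), and neither passed the correction. With the number of splicing events in the model the difference was 0.5323 (exact permutation p = 0.01). That model could hardly change it, as splicing events differed with NMN by only -33.8 per library on average (exact permutation p = 0.95). Splicing events differed by -621.7 without LPS and by 554 with LPS, while the share was higher with NMN in both, by 0.499 and 0.565. These opposite differences in size argue against the number of splicing events as the cause. A few genes with many introns are argued against too, since the share of genes with a retained intron was 0.8255 percentage points higher with NMN (exact permutation p = 0.005). Unspliced RNA or DNA in the NMN libraries may account for it and stays open: retained introns numbered 93.83 more per library with NMN (exact permutation p = 0.05, adjusted p = 0.11), 52.3 more without LPS (exact permutation p = 0.5), where skipped exons differed by -518.3 (exact permutation p = 0.5), and 135.3 more with LPS (exact permutation p = 0.1), and the files hold no reads by which to tell. An effect of NMN on splicing is a hypothesis that these catalogues cannot settle.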
